A study of Coprinopsis cinerea with 10 samples.

How the data were processed

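Total RNA of the 5 stages, with 2 biological replicates each, was hybridised to custom one-colour NimbleGen arrays after Cy3 labelling, per the labels. The strain was a fruiting dikaryon with 50% Okayama-7 origin, backcrossed to that sequenced strain for 5 generations and about 98.44% homologous to it, per the labels' protocols. Mycelium was grown at 37 °C for about 1 week on agar with yeast extract, malt extract and dextrose, and fruiting was induced at 25 °C under 12 h of light and 12 h of dark. RNA was extracted with a column kit for plant tissue. Groups and replicate numbers were taken from the sample titles and the stage label.

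The deposited values are intensity values on a linear scale, 1 per gene and block of probes, which the authors made with the robust multi-array average (RMA), as the file names give it. Per the file headers each value summarised 5 probes (fewer for 31 genes), the array held 2 blocks, and gene models and products came from the Broad Institute. The software, its version and the background and normalization settings were not given in the sources used here. The deposited intensity table of the whole series equalled the geometric mean of both blocks in every array (largest relative difference 4.98e-08%) and left out 16 genes of the mitochondrial genome. The column of standard errors that the authors deposited beside the intensity had no stated scale and was not used; the column with the number of probes was used only for the count above. The arrays had similar but not equal distributions, and a change of the total RNA content per cell was not measured.

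For each gene the log2 values of the 2 blocks were averaged per array, which gave 13320 genes on 10 arrays. No further normalization, pseudocount or filter on low values was applied. Products came from the files; 13318 genes matched locus tags of the RefSeq annotation of assembly CC3, which was used only for which genes neighbour each other, since the build behind the arrays was not given in the sources used here. Products of the array are those of its design and can be old, and probes of close paralogs, such as the pheromone or cytochrome P450 genes, can share signal. A gene was under the floor in a stage where both arrays were at or under 4 times the value of the random-sequence controls (7613 probes with 1 summary per array; floors of 89.4 to 117 intensity units); this rule was chosen after the data were seen. A fold against a stage under the floor is given as "at least N-fold", from the mean log2 level of the brighter stage against, for each array, the higher of the floor and the measured value. No fold is given where both stages were under it. The number of arrays limits the precision.

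Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes). All 10 arrays entered 1 fit with the stage as the only term, which left 5 residual degrees of freedom, and the Benjamini-Hochberg adjusted p threshold was 0.05 over all genes of a comparison. The comparisons were the 4 steps between neighbouring stages, mature cap against mycelium, and young fruiting body against the mean of the other 4 stages, with an F test over all stages. The comparisons, tests, gene lists, named-gene rule and the first set of alternatives were fixed before the data were examined. The named-gene rule took, for each comparison but the last, the 3 largest rises and falls of any gene, the 6 largest rises and falls among named products, and up to 2 members with the largest change per list, among genes called and separated in all arrays of both stages. For the last comparison only the 6 named rises and falls were taken. Genes were ranked by the fitted log2 change; where a stage was under the floor only a lower bound is known, so their order is uncertain. The galectins Cgl1, Cgl2 and Cgl3 were named in any case. Some of the genes that the rule takes are not reported here.

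Gene lists were 32 patterns on the product names: cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, translation factors and tRNA synthetases, proteasome, chaperones, DNA replication, meiosis and recombination, cell cycle, histones, cytoskeleton, cell wall synthesis and hydrolysis, hydrophobins, plant cell wall degradation, laccases and secreted oxidases, lectins and toxins, cytochrome P450, sugar and MFS transporters, secreted peptidases, mating and pheromone, light sensing, respiration, glycolysis and storage sugars, fatty acid and sterol metabolism, protein kinases, FunK1 kinases, transcription factors, F-box proteins, autophagy, splicing, and antioxidant enzymes. Lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, adjusted over the 31 lists of a comparison, with an estimated correlation and fry beside it. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Some patterns took in members by other words of a product name; lists without them were an alternative.

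The share of summed intensity on genes without a named product was tested by exact permutation of the arrays.

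The tests were checked on simulated data with the 13320 genes, 200 of them changed per comparison, 50 at each fold. Of the 50 genes changed 1.1-fold, between 3 and 10 were recovered, of those changed 1.5-fold between 41 and 48, 2-fold between 46 and 50, and 4-fold between 49 and 50; 4 to 14 unchanged genes were called. In each comparison the 1 list that was moved was called with both correlations and 0 other lists were called. Unchanged genes made up 2.74% to 8.86% of the calls in a comparison. The genes were simulated independently of each other, so this check cannot tell which correlation suits the data. It gave each gene 1 spread for all stages, whereas the spread between replicates differed between stages in the data. It thus cannot test the shared estimate of the spread. It also changed far fewer genes than were called in the data.

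Alternatives were the authors' series table, quantile normalization again, median centring, leaving out the dimmest 25% of genes, eBayes with a trend or robust, the replicate number as a block, only the arrays compared, an at least 2-fold change, each array left out in turn, and for the share also log2 sums and leaving out the 100 brightest genes. Added after the data were seen were a filter at 4 times the random controls in at least 2 arrays, each block alone, lists without stray members, and mycelium, initials and young fruiting body pairs averaged to 1 sample each. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Gene ages and sequence divergence were not analysed here.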

Results

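Transcript levels were measured in the mushroom Coprinopsis cinerea, an ink cap that completes its fruiting cycle on agar, on 10 one-colour NimbleGen arrays. Each of 5 developmental stages was represented by 2 biological replicates: vegetative mycelium, fruiting initials about 2 mm tall, stage 2 primordia about 1 cm tall, young fruiting bodies about 2 cm tall, and the fully expanded cap of mature fruiting bodies about 4 cm tall. A mycelium replicate pooled the growth of 5 plates, and a replicate of any other stage held 4 to 5 structures. The mature sample was cap tissue alone, so tissue and stage were not separable there. Values were available for 13320 genes, of which 4328 had a named product and 8992 (67.5%) were listed only as predicted or hypothetical proteins.

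The median intensity per array lay between 3268 and 3403, and the random-sequence control probes lay between 22.4 and 29.1. Between 1893 and 2137 genes per array were at or under 4 times the control value, taken as the floor, and 1468 genes were under it on all 10 arrays. The replicates of a stage correlated across genes at r between 0.997 and 0.999. Neighbouring stages correlated at 0.929 (mycelium and initials), 0.987 (initials and primordium), 0.988 (primordium and young fruiting body) and 0.907 (young fruiting body and mature cap). The spread between replicates was 2.38 times that expected from the 2 blocks of probes within an array for primordia and 2.32 times for mature caps, but only 1.25 times for mycelium, 1.13 times for initials and 1.17 times for young fruiting bodies. The replicates of those 3 stages thus differed by little more than the noise within arrays, and all stages shared 1 estimate of the spread. All 10 arrays lay on 1 slide in the order of the stages, so slide position and stage could not be told apart. Log2 changes of genes are given ± SE from limma, with n = 2 arrays per stage, and means of gene lists ± SD over the members.

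Fruiting initials had higher galectin-1, galectin-2 and Spo11 than mycelium. They had lower levels of 4 of the 5 listed hydrophobins and of 26 of 46 mating and pheromone genes. Galectin-1 (CC1G_05003), a fruiting body lectin that binds beta-galactosides, rose from a log2 intensity of 11.64 to 13.86, a change of 2.22 ± 0.0626 (adjusted p = 1.82e-07). The related galectin-2 (CC1G_05005) rose by 0.58 ± 0.0532, while the lectin CGL3 (CC1G_00723) changed by 0.12 ± 0.195 (adjusted p = 0.618) and did not pass. Spo11 (CC1G_03320), the nuclease that makes the meiotic DNA breaks, rose at least 9.85-fold from under the floor. In total 4993 genes rose and 4483 fell, of which 1200 rose and 1451 fell at least 2-fold.

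Among named products, the largest fitted rises were in a cytochrome P450 (CC1G_14898, at least 65.7-fold), a CBS domain protein (CC1G_14321, 6.57 ± 0.0523), a nitroreductase (CC1G_14853, 5.85 ± 0.108), an AgaK1-type protein kinase (CC1G_07751, at least 23.2-fold), a kynurenine aminotransferase (CC1G_15151, from under the floor to 10.43) and a phosphatidylserine decarboxylase (CC1G_09238, 5.25 ± 0.0566). The largest fitted falls were in an alcohol dehydrogenase (CC1G_14930, -5.26 ± 0.115), a peroxidase (CC1G_02104, at least 24.2-fold lower), a metalloprotease (CC1G_02236, at least 12.4-fold lower), an exo-beta-1,3-glucanase (CC1G_08284, -4.86 ± 0.151), a tyrosinase-domain protein (CC1G_06016, -4.85 ± 0.195) and a ThiJ/PfpI family protein (CC1G_10162, at least 21.4-fold lower). All adjusted p-values of these genes were at most 1.53e-06. Among genes without a named product, CC1G_05060 rose by 7.03 ± 0.0319, CC1G_14899 rose at least 52.0-fold and CC1G_09479 at least 83.9-fold. CC1G_05863 was at least 66.4-fold lower, CC1G_02761 at least 48.8-fold lower and CC1G_02118 at least 37.3-fold lower.

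Of the 5 listed hydrophobins, secreted proteins that coat hyphae, 4 fell at least 2-fold and 1 rose (1 and 4 adjusted over the list alone). The list holds only genes matched by product name and can miss members of the family. Hydrophobins CC1G_02182 and CC1G_08314 changed by -2.67 ± 0.0810 and -2.04 ± 0.0589. Hydrophobins changed by a mean log2 of -1.58 ± 1.03 (camera adjusted p = 0.0452, adjusted p = 0.326 with an estimated correlation). This call was lost with the replicate number as a block. In the mating and pheromone list, 13 of 46 rose and 26 fell (13 and 26 adjusted over the list alone). The pheromone genes CC1G_14010 and CC1G_14008 changed by -3.29 ± 0.0771 and -3.27 ± 0.0400. Mating and pheromone genes changed by a mean log2 of -0.75 ± 1.53 (camera adjusted p = 0.0365, adjusted p = 0.353 with an estimated correlation). Among antioxidant enzymes, 9 of 34 rose and 21 fell (9 and 21 adjusted over the list alone). A Cys 2 peroxiredoxin (CC1G_04730) changed by -2.45 ± 0.0768 and a catalase (CC1G_05908), which breaks down hydrogen peroxide, by -2.04 ± 0.0522. Antioxidant enzymes changed by a mean log2 of -0.46 ± 0.87 (camera adjusted p = 0.0365, adjusted p = 0.562 with an estimated correlation). The lectins and toxins had 4 of 7 members up and 0 down (4 and 0 adjusted over the list alone), including a hemolysin (CC1G_02801, 1.71 ± 0.0699), but the list did not pass (camera adjusted p = 0.118).

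The protein synthesis genes moved by small amounts in large numbers. Of the cytosolic ribosomal proteins, 0 of 80 rose and 66 fell (0 and 70 adjusted over the list alone). Cytosolic ribosomal proteins changed by a mean log2 of -0.23 ± 0.14 (camera adjusted p = 5.01e-07, adjusted p = 0.572 with an estimated correlation). Protein L19 (CC1G_01249) fell by 0.64 ± 0.0434. Mitochondrial ribosomal proteins fell too: 1 of 19 rose and 16 fell (1 and 16 adjusted over the list alone). Mitochondrial ribosomal proteins changed by a mean log2 of -0.29 ± 0.27 (camera adjusted p = 0.00181, adjusted p = 0.42 with an estimated correlation). Respiration genes, of the citric acid cycle and the electron transport chain, showed the same direction, as 5 of 64 rose and 43 fell (5 and 43 adjusted over the list alone). Respiration genes changed by a mean log2 of -0.16 ± 0.28 (camera adjusted p = 0.00103, adjusted p = 0.326 with an estimated correlation). A malate dehydrogenase (CC1G_07719) fell by 1.28 ± 0.0708. Ribosome biogenesis genes went up: 27 of 35 rose and 1 fell (27 and 1 adjusted over the list alone). Ribosome biogenesis genes changed by a mean log2 of 0.21 ± 0.38 (camera adjusted p = 0.00148, adjusted p = 0.326 with an estimated correlation). The single fall there, of ribosome assembly protein 4 (CC1G_13125), was -1.67 ± 0.0678, and the U3 snoRNA-associated protein 11 (CC1G_01799) rose by 0.72 ± 0.0334.

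Splicing factors and transcription factors were also called up against mycelium. For splicing, 38 of 61 rose and 6 fell (38 and 6 adjusted over the list alone). Splicing factors changed by a mean log2 of 0.14 ± 0.25 (camera adjusted p = 0.0352, adjusted p = 0.326 with an estimated correlation). The factor CLF1 (CC1G_08670) rose by 1.55 ± 0.0502. For transcription factors, 27 of 42 rose and 6 fell (27 and 7 adjusted over the list alone). Transcription factors changed by a mean log2 of 0.14 ± 0.40 (camera adjusted p = 0.0365, adjusted p = 0.326 with an estimated correlation). An RNA polymerase III factor (CC1G_02240) rose by 1.16 ± 0.125. Enzymes that degrade plant cell walls went both ways, 30 of 59 up and 24 down, with a mean below 0 and a median above it (camera adjusted p = 0.611). A cutinase (CC1G_09668) fell by 4.27 ± 0.159 and cellobiohydrolase I-I (CC1G_12980) rose by 3.20 ± 0.0655. Of the 9 lists called in this comparison, none passed with an estimated correlation. With the filter at 4 times the controls 4 passed, without the dimmest genes 6 (hydrophobins, splicing and transcription factors lost), and without mycelium replicate 2 there were 7 (splicing and transcription factors lost).

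Primordia differed from initials by about as many rises as falls, most of them below 2-fold, with genes of ribosomes, the proteasome and meiosis among the rises. Spo11 (CC1G_03320) rose from a log2 intensity of 9.92 to 11.27, a change of 1.34 ± 0.104 (adjusted p = 0.000129). A cyclin (CC1G_09963), of the family that drives the cell cycle kinases, rose by 2.77 ± 0.0614. In total 3135 genes rose and 3262 fell, and 297 rose and 229 fell at least 2-fold. Averaging the mycelium, initials and young fruiting body pairs to 1 sample each left 1684 genes called in place of 6397.

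Other large rises among named products were in an NADH:quinone oxidoreductase (CC1G_04039, 3.97 ± 0.0598), a thioredoxin-dependent peroxidase (CC1G_07749, at least 11.4-fold), an AGC-type protein kinase (CC1G_04354, 3.55 ± 0.0721) and a DNA helicase (CC1G_06193, 3.11 ± 0.0784). The largest fitted falls were in an ammonium transporter (CC1G_05914, -3.06 ± 0.142), a retinol dehydrogenase (CC1G_02720, -2.78 ± 0.0809), cytochromes P450 (CC1G_09431, -2.41 ± 0.124, and CC1G_01638, -2.08 ± 0.0622), an NADPH-dependent alcohol dehydrogenase (CC1G_02196, -2.35 ± 0.0433) and an integral membrane protein (CC1G_05477, -2.18 ± 0.0410). Without a named product, CC1G_06912 rose at least 31.0-fold, CC1G_05527 rose by 4.91 ± 0.155 and CC1G_12220 by 4.80 ± 0.0893, while CC1G_02661 fell by 2.96 ± 0.101 and CC1G_07100 changed by -2.93 ± 0.0851. Galectin-1 (CC1G_05003) fell by 0.21 ± 0.0626, a call lost without either replicate of the initials. Galectin-2 changed by -0.12 ± 0.0532 (adjusted p = 0.109) and CGL3 by -0.10 ± 0.195 (adjusted p = 0.71).

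Cytosolic ribosomal proteins turned round: 73 of 80 rose and 0 fell (75 and 0 adjusted over the list alone). Cytosolic ribosomal proteins changed by a mean log2 of 0.24 ± 0.094 (camera adjusted p = 7.79e-15, adjusted p = 0.294 with an estimated correlation). Protein S7 (CC1G_14669) rose by 0.52 ± 0.0403. Among mitochondrial ribosomal proteins, 17 of 19 rose and 0 fell (17 and 0 adjusted over the list alone). Mitochondrial ribosomal proteins changed by a mean log2 of 0.22 ± 0.14 (camera adjusted p = 1.91e-05, adjusted p = 0.191 with an estimated correlation). Among ribosome biogenesis genes, 28 of 35 rose and 1 fell (29 and 2 adjusted over the list alone). Ribosome biogenesis genes changed by a mean log2 of 0.20 ± 0.16 (camera adjusted p = 2.13e-06, adjusted p = 0.132 with an estimated correlation). Among translation factors and tRNA synthetases, 39 of 73 rose and 3 fell (40 and 3 adjusted over the list alone). Translation factors changed by a mean log2 of 0.11 ± 0.14 (camera adjusted p = 9.21e-06, adjusted p = 0.191 with an estimated correlation). Seryl-tRNA synthetase (CC1G_06927) rose by 0.61 ± 0.0312. Of the proteasome, the complex that degrades ubiquitin-tagged proteins, 20 of 22 rose and 1 fell (20 and 1 adjusted over the list alone). Proteasome genes changed by a mean log2 of 0.21 ± 0.18 (camera adjusted p = 6.62e-06, adjusted p = 0.191 with an estimated correlation). The exception was a 26S subunit (CC1G_10171), which fell by 0.51 ± 0.0551. Among chaperones, 37 of 71 rose and 9 fell (38 and 9 adjusted over the list alone). Chaperones changed by a mean log2 of 0.18 ± 0.30 (camera adjusted p = 0.000145, adjusted p = 0.132 with an estimated correlation). An hsp90-like protein (CC1G_05439) rose by 1.26 ± 0.0416.

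Among meiosis and recombination genes, 14 of 25 rose and 4 fell (14 and 4 adjusted over the list alone). Meiosis genes changed by a mean log2 of 0.41 ± 0.70 (camera adjusted p = 0.00669, adjusted p = 0.191 with an estimated correlation). Among cell cycle genes, 21 of 49 rose and 8 fell (23 and 8 adjusted over the list alone). Cell cycle genes changed by a mean log2 of 0.12 ± 0.45 (camera adjusted p = 0.0382, adjusted p = 0.191 with an estimated correlation). A CDC7-type kinase (CC1G_08833), of the family that fires replication origins, rose by 0.60 ± 0.0439. Among histones, 6 of 11 rose and 0 fell (6 and 0 adjusted over the list alone). Histones changed by a mean log2 of 0.11 ± 0.073 (camera adjusted p = 0.017, adjusted p = 0.309 with an estimated correlation). For respiration, 29 of 64 rose and 6 fell (32 and 7 adjusted over the list alone). Respiration genes changed by a mean log2 of 0.044 ± 0.17 (camera adjusted p = 0.0197, adjusted p = 0.304 with an estimated correlation). An NADH dehydrogenase (CC1G_06456) rose by 0.44 ± 0.0407. For splicing, 16 of 61 rose and 3 fell (10 and 2 adjusted over the list alone). Splicing factors changed by a mean log2 of 0.049 ± 0.13 (camera adjusted p = 0.0322, adjusted p = 0.191 with an estimated correlation).

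Downward, the mating and pheromone list led: 1 of 46 rose and 27 fell (1 and 28 adjusted over the list alone). Mating and pheromone genes changed by a mean log2 of -0.22 ± 0.27 (camera adjusted p = 9.97e-05, adjusted p = 0.144 with an estimated correlation). A mating-type domain protein (CC1G_14509) fell by 1.06 ± 0.104. Among cytochromes P450, 14 of 87 rose and 40 fell (14 and 41 adjusted over the list alone). Cytochromes P450 changed by a mean log2 of -0.21 ± 0.50 (camera adjusted p = 0.00404, adjusted p = 0.191 with an estimated correlation). Among cell wall synthesis genes, 4 of 36 rose and 14 fell (4 and 15 adjusted over the list alone). Cell wall synthesis genes changed by a mean log2 of -0.048 ± 0.23 (camera adjusted p = 0.0334, adjusted p = 0.191 with an estimated correlation). A chitin deacetylase (CC1G_09013) fell by 0.75 ± 0.0502. That call and those for the cell cycle and for splicing were lost without 1 initials replicate and without 1 primordium replicate. With averaged pairs 10 lists were called in place of 14, of which 8 rose and 2 fell.

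Young fruiting bodies differed from primordia by a further rise of a cyclin, while 25 of 46 mating and pheromone genes fell. The cyclin CC1G_09963 rose from 11.38 to 12.97, a log2 change of 1.59 ± 0.0614 (adjusted p = 1.33e-05). This single gene does not stand for the cell cycle list, which was not called at this step, and it was highest in the mature cap. Galectin-1 and galectin-2 changed by -0.31 ± 0.0626 (adjusted p = 0.007) and -0.34 ± 0.0532 (adjusted p = 0.00228); CGL3 changed by -0.47 ± 0.195 (adjusted p = 0.0856). In total 3194 genes rose and 3305 fell, and 344 rose and 265 fell at least 2-fold. With the pairs of 3 stages averaged as above, 2269 genes were called in place of 6499, and the calls of both galectins were lost.

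The largest fitted rises among named products were in an aryl-alcohol dehydrogenase (CC1G_14311, 2.92 ± 0.0763), the ThiJ/PfpI protein that had fallen in initials (CC1G_10162, 2.79 ± 0.114), the NADPH-dependent alcohol dehydrogenase that had fallen in primordia (CC1G_02196, 2.46 ± 0.0433), an alcohol dehydrogenase (CC1G_14930, 2.13 ± 0.115), a carboxylesterase (CC1G_05995, at least 2.75-fold) and a cellulose-growth-specific protein (CC1G_05382, at least 2.63-fold). The largest fitted falls were in LAP1 (CC1G_04948, -2.62 ± 0.194), snodprot1 (CC1G_09154, -2.18 ± 0.147), a lysyl oxidase (CC1G_07936, -2.07 ± 0.0759), a selenocysteine lyase (CC1G_03954, -1.94 ± 0.104), a glucose transporter (CC1G_07797, -1.90 ± 0.0700) and a secreted protein (CC1G_08056, -1.85 ± 0.0928). Without a named product, CC1G_14115 rose by 3.14 ± 0.152 and CC1G_15217 at least 5.81-fold, while CC1G_08239 fell by 3.67 ± 0.111, CC1G_08939 changed by -3.64 ± 0.0939 and CC1G_15270 was at least 8.16-fold lower.

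Among mating and pheromone genes, 5 of 46 rose and 25 fell (5 and 25 adjusted over the list alone). Mating and pheromone genes changed by a mean log2 of -0.25 ± 0.41 (camera adjusted p = 0.00324, adjusted p = 0.492 with an estimated correlation). The pheromone gene CC1G_15341 fell by 1.05 ± 0.0532. For splicing, 2 of 61 rose and 28 fell (2 and 28 adjusted over the list alone). Splicing factors changed by a mean log2 of -0.065 ± 0.15 (camera adjusted p = 0.0144, adjusted p = 0.492 with an estimated correlation). A U2AF-associated factor (CC1G_09327) fell by 0.38 ± 0.0346. Among cytosolic ribosomal proteins, 21 of 80 rose and 2 fell (9 and 2 adjusted over the list alone). Cytosolic ribosomal proteins changed by a mean log2 of 0.087 ± 0.095 (camera adjusted p = 0.00288, adjusted p = 0.743 with an estimated correlation). For the proteasome, 6 of 22 rose and 1 fell (6 and 1 adjusted over the list alone). Proteasome genes changed by a mean log2 of 0.10 ± 0.15 (camera adjusted p = 0.0398, adjusted p = 0.599 with an estimated correlation). The 26S subunit that fell in primordia (CC1G_10171) rose by 0.72 ± 0.0551. Among antioxidant enzymes, 17 of 34 rose and 5 fell (17 and 5 adjusted over the list alone). Antioxidant enzymes changed by a mean log2 of 0.22 ± 0.47 (camera adjusted p = 0.0454, adjusted p = 0.599 with an estimated correlation). The thioredoxin-dependent peroxidase CC1G_07749 rose by 1.81 ± 0.194. The proteasome and antioxidant calls were lost without primordium replicate 2, without young fruiting body replicate 2 and without either mature replicate. With averaged pairs 2 lists were called in place of 5, 1 up and 1 down, so a downward call was lost too. Hydrophobins CC1G_02182 and CC1G_09189 changed by -1.17 ± 0.0810 and -0.86 ± 0.0868, but the list of 5 did not pass (camera adjusted p = 0.37).

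**Figure D1:**
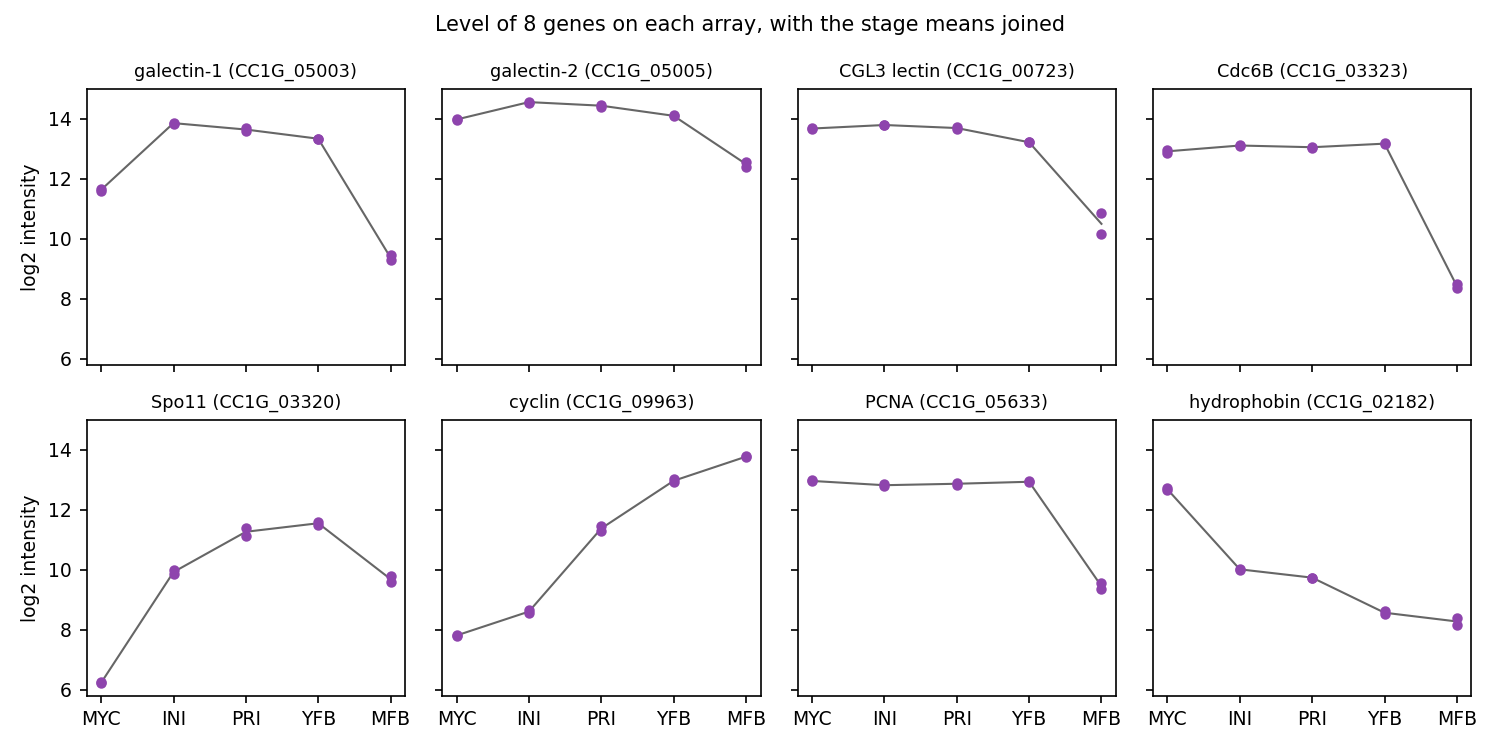
Log2 intensity (vertical axis) of 8 genes on each of the 10 arrays (points, 2 per stage) in mycelium (MYC), initials (INI), primordia (PRI), young fruiting bodies (YFB) and mature caps (MFB), with lines joining the stage means. The cyclin stood at 11.38 in primordia and 12.97 in young fruiting bodies, and galectin-1 at 13.86 in initials and 9.37 in mature caps.

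Mature caps differed from young fruiting bodies more than any other pair of neighbouring stages in counts of genes, by lower transcripts of replication, division and meiosis genes, of the galectins, of the proteasome and of ribosomes. Galectin-1 (CC1G_05003) fell by 3.97 ± 0.0626, from 13.34 to 9.37 (adjusted p = 1.25e-08), galectin-2 (CC1G_05005) changed by -1.61 ± 0.0532 and CGL3 (CC1G_00723) by -2.72 ± 0.195 (adjusted p = 1.09e-05). The cohesin subunit Rad21 (CC1G_05127), which holds sister chromatids together, fell by 2.80 ± 0.0799. A ricin B lectin (CC1G_11246) rose by 3.04 ± 0.0655 and laccase 7 (CC1G_09611), a copper enzyme that oxidises phenols, by 4.68 ± 0.0795. In total 5095 genes rose and 5422 fell, and 1639 rose and 1975 fell at least 2-fold. The balance of rises and falls depended on the scaling, as median centring gave 5486 rises and 5113 falls.

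The largest fitted rises among named products were in a protein with the G-X-X-X-Q-X-W repeat of ricin-type lectins (CC1G_02597, 6.24 ± 0.0605), mannoprotein MP88 (CC1G_07946, 5.71 ± 0.0472), a hemerythrin-domain protein (CC1G_13754, 5.43 ± 0.0995), a benzoquinone reductase (CC1G_11359, 5.24 ± 0.0549), an alginate lyase (CC1G_06067, 5.03 ± 0.0447) and a mating-type pheromone (CC1G_15337, at least 31.3-fold). The largest fitted falls were in dCMP deaminase (CC1G_01851, at least 15.0-fold lower), which supplies precursors of thymidine nucleotides, a phosphatidylserine decarboxylase (CC1G_09208, -6.65 ± 0.125), uracil-DNA glycosylase (CC1G_10296, at least 24.7-fold lower), a base excision repair enzyme, a sirtuin (CC1G_09430, at least 12.5-fold lower), a basidiospore development protein (CC1G_05700, at least 18.3-fold lower) and an ebpl-prov protein (CC1G_05046, -5.90 ± 0.129). Adjusted p-values of these 12 genes were at most 3.78e-07. Without a named product, CC1G_10253 rose at least 138-fold, CC1G_11446 at least 65.2-fold and CC1G_11070 by 6.78 ± 0.407, while CC1G_05600 was at least 66.5-fold lower and CC1G_13884 at least 14.5-fold lower.

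Genes of DNA replication were nearly all lower: 3 of 23 rose and 20 fell (3 and 20 adjusted over the list alone). DNA replication genes changed by a mean log2 of -1.46 ± 1.61 (camera adjusted p = 0.000172, adjusted p = 0.257 with an estimated correlation). The GINS subunit PSF2 (CC1G_01354), part of the replicative helicase, fell by 4.83 ± 0.199, and an origin binding protein (CC1G_05245) fell by 3.64 ± 0.0368. For meiosis and recombination, 4 of 25 rose and 20 fell (4 and 20 adjusted over the list alone). Meiosis genes changed by a mean log2 of -0.97 ± 1.06 (camera adjusted p = 0.00255, adjusted p = 0.257 with an estimated correlation). For the cell cycle, 9 of 49 rose and 34 fell (9 and 34 adjusted over the list alone). Cell cycle genes changed by a mean log2 of -0.70 ± 1.36 (camera adjusted p = 0.00325, adjusted p = 0.161 with an estimated correlation). A CDC20 family protein (CC1G_09412), of the activators of the anaphase-promoting complex, fell by 4.98 ± 0.0678. Cdc6B (CC1G_03323), a licensing factor of replication origins, fell by 4.75 ± 0.0488. Among histones, 0 of 11 rose and 9 fell (0 and 9 adjusted over the list alone). Histones changed by a mean log2 of -0.59 ± 0.88 (camera adjusted p = 0.0192, adjusted p = 0.411 with an estimated correlation). The largest fall there was of a histone H2A gene (CC1G_07640, -3.16 ± 0.0728). Among cytoskeleton genes, 7 of 47 rose and 35 fell (7 and 35 adjusted over the list alone). Cytoskeleton genes changed by a mean log2 of -0.53 ± 0.86 (camera adjusted p = 0.00105, adjusted p = 0.161 with an estimated correlation). A dynein intermediate chain (CC1G_06941) fell by 3.58 ± 0.0609.

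Of the proteasome, 1 of 22 rose and 21 fell (1 and 21 adjusted over the list alone). Proteasome genes changed by a mean log2 of -0.97 ± 0.33 (camera adjusted p = 2.81e-06, adjusted p = 0.257 with an estimated correlation). The subunits beta type 3 (CC1G_13712) and alpha type-3 (CC1G_01276) changed by -1.38 ± 0.0273 and -1.34 ± 0.0275. Of the cytosolic ribosomal proteins, 2 of 80 rose and 73 fell (2 and 74 adjusted over the list alone). Cytosolic ribosomal proteins changed by a mean log2 of -0.69 ± 0.36 (camera adjusted p = 4.37e-11, adjusted p = 0.411 with an estimated correlation). Protein L17 (CC1G_09927) fell from 13.86 to 12.36 (SE of the change 0.0474). Among ribosome biogenesis genes, 4 of 35 rose and 24 fell (4 and 24 adjusted over the list alone). Ribosome biogenesis genes changed by a mean log2 of -0.29 ± 0.67 (camera adjusted p = 0.00938, adjusted p = 0.257 with an estimated correlation). Among translation factors, 13 of 73 rose and 43 fell (13 and 43 adjusted over the list alone). Translation factors changed by a mean log2 of -0.16 ± 0.43 (camera adjusted p = 0.0236, adjusted p = 0.498 with an estimated correlation). Among secreted peptidases, 12 of 60 rose and 39 fell (12 and 39 adjusted over the list alone). Secreted peptidases changed by a mean log2 of -0.36 ± 1.39 (camera adjusted p = 0.0176, adjusted p = 0.173 with an estimated correlation). Against that direction, pepsinogen A (CC1G_11543) rose by 4.72 ± 0.0710. Respiration was the only list of 31 called up: 34 of 64 rose and 11 fell (34 and 11 adjusted over the list alone). Respiration genes changed by a mean log2 of 0.20 ± 0.43 (camera adjusted p = 0.0445, adjusted p = 0.411 with an estimated correlation). Its call was lost with the authors' table that leaves out the mitochondrial genome, after repeated quantile normalization and with only the arrays compared. It was also lost with the replicate number as a block, without stray members and with averaged pairs. Nor did it hold without either mycelium replicate, young fruiting body replicate 1 or mature replicate 1. The call of translation factors was lost after median centring, without the dimmest genes and with the filter at 4 times the controls.

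Groups that did not pass as lists still held large changes of single genes. Of the 30 laccases and secreted oxidases, 18 rose and 12 fell, 13 and 7 of them at least 2-fold (18 and 12 adjusted over the list alone, camera adjusted p = 0.325), and a copper radical oxidase (CC1G_10353) fell by 4.64 ± 0.0593. The lectins and toxins had 1 rise and 5 falls among 7 (1 and 6 adjusted over the list alone, camera adjusted p = 0.119). Mating and pheromone genes split into 27 up and 17 down, 20 and 12 of them at least 2-fold (27 and 17 adjusted over the list alone, camera adjusted p = 0.323), and the pheromone gene CC1G_02130 fell by 3.84 ± 0.0979. Among chaperones, 22 of 71 rose and 37 fell (22 and 37 adjusted over the list alone, camera adjusted p = 0.325), with small heat shock proteins CC1G_05868 and CC1G_02341 up by 4.87 ± 0.117 and 3.58 ± 0.0815. Plant cell wall degradation had 23 of 59 up and 30 down (23 and 30 adjusted over the list alone, camera adjusted p = 0.843), with rhamnogalacturonase B (CC1G_05304) changed by -3.94 ± 0.117.

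**Figure D2:**
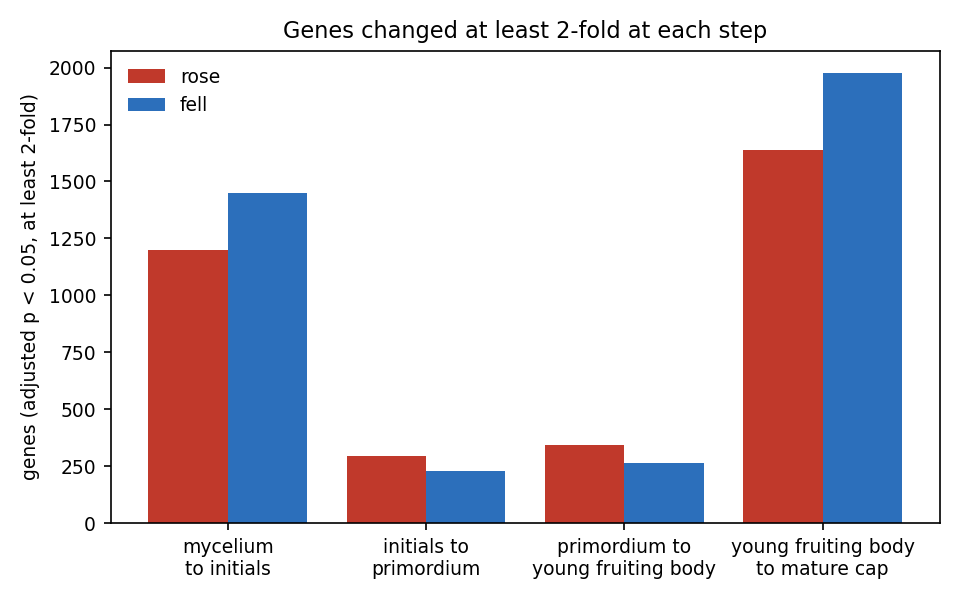
Numbers of genes (vertical axis, from 0) with an adjusted p under 0.05 and at least a 2-fold change that rose or fell at each step between neighbouring stages. The step to initials held 1200 rises and 1451 falls, the middle steps at most 344 of either, and the step to the mature cap 1639 and 1975.

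Set against mycelium, the starting point of the cycle, mature caps differed in 10747 genes, of which 1973 rose and 2263 fell at least 2-fold. All 5 listed hydrophobins were lower, 4 of them at least 2-fold (0 and 5 adjusted over the list alone). Hydrophobins changed by a mean log2 of -2.63 ± 1.49 (camera adjusted p = 0.0187, adjusted p = 0.283 with an estimated correlation). CC1G_02182 fell by 4.41 ± 0.0810 and hydrophobin-315 (CC1G_09189) fell by 3.38 ± 0.0868. The cyclin CC1G_09963 rose by 5.97 ± 0.0614 and was highest in the mature cap, whereas the replication clamp PCNA (CC1G_05633) fell by 3.51 ± 0.0700 and Cdc6B (CC1G_03323) fell by 4.50 ± 0.0488. Spo11 (CC1G_03320) was still at least 8.36-fold above mycelium. All 3 of the named lectins were lower than in mycelium: galectin-1 changed by -2.27 ± 0.0626, galectin-2 by -1.49 ± 0.0532 and CGL3 by -3.18 ± 0.195.

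The largest fitted rises among named products were in the peptide transporter MTD1 (CC1G_02463, at least 215-fold), a small heat shock protein (CC1G_05868, at least 133-fold), the cytochrome P450 and the AgaK1-type kinase that had risen in initials (CC1G_14898, at least 142-fold, and CC1G_07751, at least 64.6-fold), the G-X-X-X-Q-X-W protein (CC1G_02597, 7.11 ± 0.0605) and a lysozyme (CC1G_03076, at least 91.9-fold). The largest fitted falls were in an epoxide hydrolase (CC1G_09851, at least 89.7-fold lower), dCMP deaminase (CC1G_01851, to under the floor), a mannanase (CC1G_02860, -6.87 ± 0.139), snodprot1 (CC1G_09154, at least 51.3-fold lower), the ebpl-prov protein (CC1G_05046, -6.30 ± 0.129) and a cytochrome P450 (CC1G_04797, at least 32.6-fold lower). Among genes without a named product, CC1G_03184 rose at least 315-fold, CC1G_14899 at least 154-fold and CC1G_10253 at least 128-fold, while CC1G_06081 was at least 82.6-fold lower, CC1G_09496 at least 41.9-fold lower and CC1G_15270 at least 41.7-fold lower.

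Besides hydrophobins, 4 lists were called, all downward. Among cytosolic ribosomal proteins, 3 of 80 rose and 73 fell (3 and 73 adjusted over the list alone). Cytosolic ribosomal proteins changed by a mean log2 of -0.59 ± 0.33 (camera adjusted p = 1.44e-09, adjusted p = 0.586 with an estimated correlation). For the proteasome, 1 of 22 rose and 21 fell (1 and 21 adjusted over the list alone). Proteasome genes changed by a mean log2 of -0.62 ± 0.33 (camera adjusted p = 0.00014, adjusted p = 0.284 with an estimated correlation). For DNA replication, 3 of 23 rose and 20 fell (3 and 20 adjusted over the list alone). DNA replication genes changed by a mean log2 of -1.09 ± 1.54 (camera adjusted p = 0.000896, adjusted p = 0.283 with an estimated correlation). Among mating and pheromone genes, 10 of 46 rose and 30 fell (10 and 31 adjusted over the list alone). Mating and pheromone genes changed by a mean log2 of -0.87 ± 2.16 (camera adjusted p = 0.00473, adjusted p = 0.283 with an estimated correlation). The pheromone gene CC1G_02130 fell by 5.07 ± 0.0979, while pheromone-regulated membrane protein 10 (CC1G_01756) rose at least 28.0-fold. The 87 cytochromes P450 had 26 up and 52 down (26 and 54 adjusted over the list alone) and did not pass as a list (camera adjusted p = 0.0888). Plant cell wall enzymes had 29 up and 20 down, with the mean below 0 and the median above it (camera adjusted p = 0.626).

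The title of the study names a developmental hourglass, the idea that a middle stage of development is the most conserved. Gene ages were not used here, and the young fruiting body was set against the mean of the other 4 stages by expression alone. Against that mean it was high in an AGC-type protein kinase (CC1G_04354, 3.12 ± 0.0570), glycosyltransferase 2 (CC1G_14858, 3.41 ± 0.122) and a copper radical oxidase (CC1G_01224, 3.09 ± 0.0851). The basidiospore development protein (CC1G_05700, at 10.96, and under the floor in mature caps) and a laccase (CC1G_03940, 2.83 ± 0.0507) were high too. It was low in 3 cytochromes P450 (CC1G_09431, -3.47 ± 0.0983, CC1G_10879, -2.96 ± 0.0956, and CC1G_07782, -2.74 ± 0.0439) and an oxidoreductase with a Rossmann fold (CC1G_11777, -3.33 ± 0.0911). The CoH1 protein (CC1G_02184, -2.94 ± 0.156) and an oxidoreductase annotated also as a P450 monooxygenase (CC1G_10409, -2.43 ± 0.0609) were low too. Such differences need not be particular to the young fruiting body. The kinase had already risen from initials to primordia. CC1G_09431 was at 7.13 in primordia and 6.85 in young fruiting bodies, and CC1G_10879 at 7.92 and 6.79. Galectin-1 was higher by 1.21 ± 0.0495, galectin-2 by 0.23 ± 0.0421 (adjusted p = 0.00204, lost with averaged pairs), and CGL3 differed by 0.30 ± 0.154 (adjusted p = 0.119). In total 5028 genes were higher and 4418 lower, and 689 and 717 of them at least 2-fold. With averaged pairs 6285 genes were called in place of 9446.

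Lists of protein synthesis and of the proteasome lay above the mean of the other 4 stages in the young fruiting body, while mitochondrial ribosomal proteins had 8 higher and 4 lower of 19 (8 and 3 adjusted over the list alone) and were not called (camera adjusted p = 0.514). Among cytosolic ribosomal proteins, 70 of 80 were higher and 2 lower (70 and 3 adjusted over the list alone). Cytosolic ribosomal proteins differed by a mean log2 of 0.30 ± 0.17 (camera adjusted p = 2.18e-09, adjusted p = 0.44 with an estimated correlation). Among proteasome genes, 21 of 22 were higher and 0 lower (21 and 0 adjusted over the list alone). Proteasome genes differed by a mean log2 of 0.44 ± 0.14 (camera adjusted p = 2.09e-06, adjusted p = 0.24 with an estimated correlation). Among ribosome biogenesis genes, 30 of 35 were higher and 2 lower (30 and 2 adjusted over the list alone). Ribosome biogenesis genes differed by a mean log2 of 0.24 ± 0.35 (camera adjusted p = 4.06e-05, adjusted p = 0.154 with an estimated correlation). Their mean log2 levels over the 5 stages in order were 11.76, 11.97, 12.16, 12.19 and 11.90, so the young fruiting body was close to primordia and mycelium was lowest. Among translation factors, 49 of 73 were higher and 9 lower (49 and 9 adjusted over the list alone). Translation factors differed by a mean log2 of 0.12 ± 0.20 (camera adjusted p = 0.00241, adjusted p = 0.39 with an estimated correlation). The low mature cap carried much of the difference for the ribosomal proteins and the proteasome, whose mean log2 levels over the 5 stages in order were 13.21, 12.98, 13.22, 13.31 and 12.62, and 12.90, 12.94, 13.15, 13.26 and 12.28.

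Among DNA replication genes, 20 of 23 were higher and 2 lower (20 and 2 adjusted over the list alone). DNA replication genes differed by a mean log2 of 0.56 ± 0.55 (camera adjusted p = 0.000147, adjusted p = 0.24 with an estimated correlation). The low mature cap carried much of this: their mean log2 level was 11.88 in mycelium, 11.99 in initials, 12.11 in primordia, 12.26 in young fruiting bodies and 10.79 in mature caps. Among meiosis and recombination genes, 19 of 25 were higher and 3 lower (19 and 3 adjusted over the list alone). Meiosis genes differed by a mean log2 of 0.62 ± 0.81 (camera adjusted p = 0.00187, adjusted p = 0.24 with an estimated correlation). Their mean log2 levels, stages in order, were 11.33, 11.77, 12.18, 12.27 and 11.30, lowest in mycelium and mature caps. Among cell cycle genes, 31 of 49 were higher and 12 lower (33 and 12 adjusted over the list alone). Cell cycle genes differed by a mean log2 of 0.30 ± 0.57 (camera adjusted p = 0.0063, adjusted p = 0.154 with an estimated correlation). Among cytoskeleton genes, 31 of 47 were higher and 3 lower (31 and 3 adjusted over the list alone). Cytoskeleton genes differed by a mean log2 of 0.18 ± 0.30 (camera adjusted p = 0.00187, adjusted p = 0.154 with an estimated correlation). The low mature cap also carried much of these differences: mean log2 levels over the 5 stages in order were 12.19, 12.24, 12.36, 12.43 and 11.73 for the cell cycle, and 12.64, 12.69, 12.73, 12.75 and 12.21 for the cytoskeleton. Among histones, 9 of 11 were higher and 0 lower (9 and 0 adjusted over the list alone). Histones differed by a mean log2 of 0.20 ± 0.20 (camera adjusted p = 0.0457, adjusted p = 0.44 with an estimated correlation). Histones were no higher than in primordia (13.64 against 13.66) and lowest in mature caps (13.06). The mating and pheromone list was the only one called low. Of its 46 members, 9 were higher and 28 lower (9 and 28 adjusted over the list alone). Mating and pheromone genes differed by a mean log2 of -0.58 ± 0.78 (camera adjusted p = 0.00178, adjusted p = 0.199 with an estimated correlation). Their mean log2 levels, stages in order, were 11.26, 10.51, 10.29, 10.04 and 10.40, so high mycelium carried much of this. The call for histones was lost without either mycelium replicate, either primordium replicate or young fruiting body replicate 2, after median centring, without the dimmest genes, with the filter at 4 times the controls, with either block of probes alone and with averaged pairs.

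**Figure D3:**
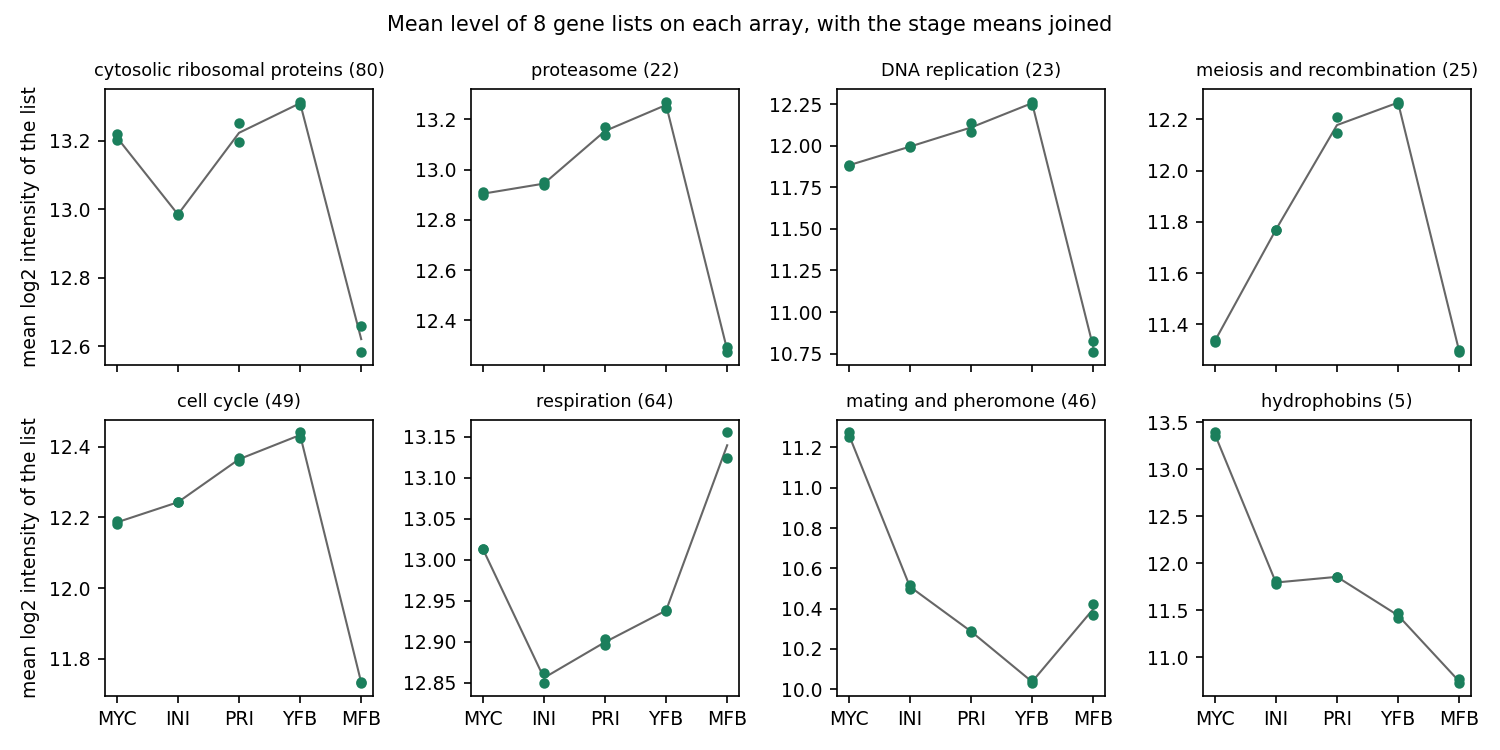
Mean log2 intensity (vertical axis) of the members of 8 gene lists on each array (points, 2 per stage) in mycelium (MYC), initials (INI), primordia (PRI), young fruiting bodies (YFB) and mature caps (MFB), with lines joining the stage means and the number of members in brackets. The vertical scales differ between panels; DNA replication changed by -1.46 on average from young fruiting body to mature cap and hydrophobins by -1.58 from mycelium to initials.

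Over all 5 stages 11963 genes (89.8%) varied in limma's F test, 6289 of them with at least a 2-fold range between stage means. Of these 6289, 2069 were highest in mature caps, 2001 in mycelium, 1116 in young fruiting bodies, 788 in initials and 315 in primordia. The first 3 principal components of the arrays held 49.9%, 37.1% and 9.78% of the variance.

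Genes without a named product carried 53.4% ± 0.00873 (SD, n = 2) of the summed intensity in young fruiting bodies, the lowest of the 5 stages. The share was 54.8% ± 0.0306 in mycelium, 54.5% ± 0.00958 in initials, 53.7% ± 0.112 in primordia and 55.0% ± 0.0135 in mature caps. The stages differed in an exact permutation test of F over the 945 splits of the arrays into pairs (p = 0.00106, the smallest these splits can give). The young fruiting body arrays lay -1.17 percentage points from the other 8 arrays (exact permutation, two-sided p = 0.0222, the smallest of 45 splits). The range over stages, 1.69 points, was small against the share itself, and a lack of a product name is no measure of gene age.

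**Figure D4:**
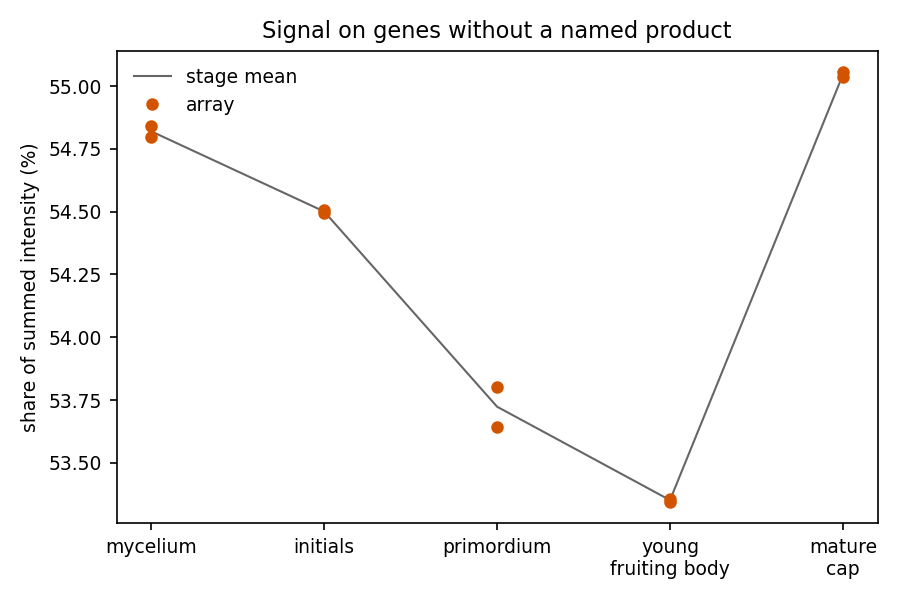
Share of the summed intensity of an array (vertical axis, percent, not starting at 0) carried by the 8992 genes without a named product, for each array (points, 2 per stage), with a line through the stage means. Young fruiting bodies lay lowest at 53.4% and mature caps highest at 55.0%.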

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

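Chosen only after the data were seen were the filter at 4 times the random controls, each block of probes alone, lists without stray members, and the pairs averaged. Genes near the controls limit the values: between 1893 and 2137 of 13320 genes per array were at or under the floor. The planned filter on the 95th percentile of the random controls was not run, because the files used here give 1 summary of these probes per array. Where 1 array was left out, the lone array of its stage was assumed to vary like the other stages.

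Requiring at least a 2-fold change besides the adjusted p left 2651 of 9476 genes for initials against mycelium, 526 of 6397 for primordium against initials, 609 of 6499 for young fruiting body against primordium, 3614 of 10517 for mature cap against young fruiting body, 4236 of 10747 for mature cap against mycelium, 1406 of 9446 for young fruiting body against the others, and 6289 of 11963 over all stages. The stricter threshold is the cause by construction. With the pairs of mycelium, initials and young fruiting body averaged, 1684 genes were called for primordium against initials, 2269 for young fruiting body against primordium and 6285 for young fruiting body against the others; fewer samples entered the fit. Every other count of genes stayed within 1.5 times, though that of initials against mycelium with averaged pairs only narrowly. Median centring moved the balance to 2894 rises and 3531 falls for primordium against initials, from 3135 and 3262, and turned it for mature cap against young fruiting body, to 5486 and 5113 from 5095 and 5422. Over single arrays left out, the counts ranged over 8551 to 9704, 4535 to 6944, 4712 to 7003, 9813 to 10530, 10293 to 10792 and 8102 to 9621 in the order of the comparisons, and over 11754 to 12071 for all stages.

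With an estimated correlation camera called 0 lists in each of the 6 comparisons, where 2, 7, 2, 4, 4 and 6 lists had an unadjusted p under 0.05. The preset correlation had called 9, 14, 5, 11, 5 and 10. Fry, which does not compare a list with other genes, called 27, 27, 19, 27, 29 and 29. In 7 cases fry called the direction opposite to that of camera, which had not called the list. Their mean log2 changes were -0.11 for cytochrome P450 in initials against mycelium, 0.027 for cell wall hydrolysis in primordium against initials, -0.18 for fatty acid and sterol metabolism in mature cap against young fruiting body, and 0.087 for laccases in young fruiting body against the others. In mature cap against mycelium they were -0.039 for meiosis, 0.096 for cell wall synthesis and -0.15 for sugar transporters. The cause was not tested. For young fruiting body against primordium, 3 lists passed in place of 5 without the dimmest 25% of genes, with only the arrays compared and with the filter at 4 times the controls, and 2 with averaged pairs; single arrays left out gave 3 to 6. The count of 3 came without primordium replicate 2, young fruiting body replicate 2 or either mature replicate. For initials against mycelium, 4 lists passed in place of 9 with the filter at 4 times the controls. The cause was not tested.

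The replicate numbers were not taken to pair the samples. Replicate differences of 10 pairs of stages correlated at r between -0.0237 and 0.503, over 0.1 for most pairs but at or under it for 2, and every pair was required to exceed it. With the number as a block, 9496, 6343, 6505, 10598, 10831 and 9536 genes were called, all within 1.5 times of the counts without it. Lists called with the block were 8, 14, 5, 10, 5 and 10; the calls lost were hydrophobins in initials against mycelium and respiration in mature cap against young fruiting body.

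The share of signal on genes without a named product ranged over stages by 1.69 to 1.70 points when single arrays were left out, and the young fruiting body lay -1.30 to -1.10 points from the others. Without either of its own replicates the difference was -1.18 or -1.17 and the exact p 0.111, the smallest that 1 array against 8 can give. As a share of the summed log2 values the difference was -0.156 points (exact p = 0.0444).

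For the genes named, 8805 combinations of gene, comparison and alternative kept the outcome, 112 lost the call, 16 gained it and 0 reversed. Keeping the outcome meant a call in the same direction, or no call in either fit whatever the direction. The rule took mostly genes with the largest called changes, so this stability was largely built in. For single lists, 3996 kept the outcome, 136 lost the call, 108 gained it and 7 reversed, those above. The 3996 include lists called in neither fit: with the estimated correlation, which called 0 lists, 132 counted as kept.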

Other observations

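The tests of the 100 brightest genes and of drift along the slide were chosen only after the results they address were seen, and the 3 patterns weighed were picked after the data were seen. Several fixed lists were not called in any comparison but held members with large changes. From young fruiting body to mature cap 5095 of all 13320 genes rose and 5422 fell (79.0% called). Many calls in both directions were thus not particular to the lists given here for that step. Glycolysis and storage sugar genes had 16 up and 13 down (16 and 13 adjusted over the list alone; camera adjusted p = 0.655) of 33 from young fruiting body to mature cap, and a glyceraldehyde 3-phosphate dehydrogenase (CC1G_09117) rose by 3.91 ± 0.0464 and mannitol-1-phosphate dehydrogenase (CC1G_07718) by 1.78 ± 0.0411. Fatty acid and sterol genes had 34 up and 38 down (34 and 38 adjusted over the list alone; camera adjusted p = 0.997) of 87 at that step, where a fatty acid conjugase (CC1G_02589) fell by 5.35 ± 0.261 and its neighbour, a delta 12 fatty acid epoxygenase (CC1G_02590), was at least 26.8-fold lower. Cell wall hydrolysis had 16 up and 13 down (16 and 13 adjusted over the list alone; camera adjusted p = 0.633) of 36: lysozyme CC1G_03076 rose by 3.63 ± 0.0768 and lysozyme CC1G_03049 was at least 15.3-fold lower. Sugar and MFS transporters had 9 up and 10 down (9 and 10 adjusted over the list alone; camera adjusted p = 0.932) of 21, with the mean above 0 and the median just below it; sugar transporter 1 (CC1G_08389) rose by 2.98 ± 0.0297.

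Protein kinases had 98 up and 116 down (98 and 116 adjusted over the list alone; camera adjusted p = 0.932) of 273 from young fruiting body to mature cap, and the fungal FunK1 kinases 42 up and 52 down (40 and 52 adjusted over the list alone; camera adjusted p = 0.823) of 127; in both the mean lay below 0 and the median above it. FunK1 gene CC1G_10359 was at least 13.6-fold lower and CC1G_07435 rose by 3.56 ± 0.104. F-box proteins, which choose targets for ubiquitin ligases, had 3 up and 4 down (3 and 4 adjusted over the list alone; camera adjusted p = 0.932) of 9, again with mean and median of opposite sign, and autophagy genes 3 up and 3 down (3 and 3 adjusted over the list alone; camera adjusted p = 0.932) of 6. Both light sensing genes rose from mycelium to initials, a photolyase (CC1G_14649) by 1.36 ± 0.0553 and photoreceptor A (CC1G_08609) by 0.72 ± 0.0300 (2 of 2 adjusted over the list alone, too few members for a list test). Light and temperature also differed between these stages. Of the 16 genes of the mitochondrial genome, 14 rose and 0 fell from young fruiting body to mature cap, with a mean log2 change of 0.59 ± 0.39 (SD over genes); this set was chosen after its values were seen.

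The first pattern weighed is the low share of signal on genes without a named product in the young fruiting body, -1.17 points from the other arrays. The 100 brightest genes do not account for it (-1.17 points without them), nor do genes of translation alone (-0.941 points without 207 such genes). The exact p without the brightest genes, 0.0222, has the limit given above, since it treats the arrays of a stage as exchangeable with all others. A one-way drift along the slide cannot alone give the whole course, since the lowest mature array lay 1.68 points above the highest young one. Drift can still have lowered the young arrays, because the stage means fell in slide order from mycelium (54.8%) to young fruiting bodies (53.4%). A lower signal of the unnamed genes themselves stays open: among genes of like level they changed by -0.040 log2 against named genes, inside the range of 1000 shuffles of the naming (-0.054 to 0.038), although few shuffles lay as far from 0 (permutation p = 0.005). Effects of slide position and of the stage itself were not tested apart from each other.

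The second pattern is that changes from mycelium to initials tended to turn round from young fruiting body to mature cap. These comparisons share no arrays, but initials and young fruiting bodies correlated at 0.966 and enter them with opposite sign. A negative r can thus arise from a deviation that these middle stages share, even if mycelium and mature cap are unrelated. Across genes, which are not independent replicates, r was -0.121. It lay below all 1000 shuffles among genes of like level in the young fruiting body (-0.0909 to -0.0200, permutation p = 0.001, the smallest they can give). Bounds on a gene's level thus do not account for all of it. The shuffles do not hold each gene's own baseline fixed. They cannot tell a link between the 2 changes from the likeness of the middle stages, which also bears on the 2-fold counts below. Over the 10627 genes above the floor on all arrays r was -0.165, against genes near the background as the cause, while Spearman's rho over all genes was -0.0768. At 2-fold, 441 genes fell and then rose where independent lists would share 179, and 377 rose and then fell against 178, but genes moving the same way were also in excess (225 against 148 and 330 against 215); 13 of the 46 mating and pheromone genes fell and then rose. No biological explanation was tested, and the cap-only tissue of the mature sample stays open. So does the different temperature and light of the mycelium.

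The third pattern is that genes next to each other on a chromosome changed together from young fruiting body to mature cap, with r = 0.165 over 13303 pairs of neighbours in the assembly CC3 (shuffled orders gave -0.0254 to 0.0259). It was not special to this step, as r was 0.177 from mycelium to initials, 0.123 from initials to primordia, 0.140 from primordia to young fruiting bodies and 0.191 between mycelium and mature cap; the tests address this step only. The 1543 pairs with different named products gave r = 0.142 (shuffles -0.0852 to 0.0794, permutation p = 0.001, the smallest they can give). Different here means only that the product names shared no telling word, as no sequences or probes were compared. Copies with like names thus do not account for the correlation in those pairs. Copies with unlike names can remain among them, so probes shared by copies stay open. The other pairs were not cleared of copies by name either. Placement on the array stays open. The replicate differences of the mature stage gave r = 0.0575 between neighbours, over the highest r of shuffled orders but well under 0.165. An effect shared by both mature arrays cancels in these differences, so they cannot show how large a part placement had. There were 48 runs of at least 4 neighbours that changed at least 2-fold the same way, 21 up and 27 down. Shuffles gave a mean of 8.10 and at most 17. The run from Spo11 (CC1G_03320) to Cdc6B (CC1G_03323) fell, and the run from CC1G_11246, the ricin B lectin, to CC1G_11248 rose. Other runs held genes of like product, such as the phosphatidylserine decarboxylases CC1G_09240, CC1G_09238 and CC1G_09237, which fell. Another held pheromone and receptor genes from CC1G_02135 to CC1G_15340 and also fell. Copies of a gene were not left out of the runs, and these examples were chosen after their values were seen. Neither a biological explanation nor overlapping gene models were tested.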
